A study of Mus musculus with 2 samples.

How the data were processed

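Immune cells from the thymus of wild-type mice and of mice with a conditional knockout of Rpa1 were profiled by droplet single-cell RNA sequencing with the 10x 3' chemistry, per the labels' protocols. Rpa1 encodes the large subunit of replication protein A, which binds single-stranded DNA. The series holds 1 library per group, so 2 libraries were compared. The labels give the strain of both as C57BL/6. They do not name the deleted part of the gene or the cells in which it was deleted.

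The authors deposited, for each library, a matrix of UMI counts per gene and barcode, with 32285 gene rows. The matrix headers name Cell Ranger 5.0.0. The submitters' processing notes list Cell Ranger 5.0.0, Seurat 4.0.3 and the mm10 build without saying which step used which. The deposited values were whole numbers and were used as counts without further scaling. The WT library held 4912 barcodes and 34165359 UMIs, and the knockout library held 5077 barcodes and 37912039 UMIs. Gene positions are from the GENCODE vM21 annotation of GRCm38, the same assembly as mm10, in which 32158 of the 32285 gene IDs had a position.

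Barcodes were kept with at least 500 genes and at most 10% of UMIs from mitochondrially encoded genes. Scrublet, run in scanpy 1.11.5 on each library alone, called 3 WT and 2 knockout barcodes, which is 0.0622% and 0.0402% of those tested, so its threshold had not worked. The fallback fixed for that case was applied, and the 193 WT and 206 knockout barcodes with the highest scores were taken out, matching an expected rate of 0.8% per 1000 barcodes. This left 4628 WT and 4767 knockout cells.

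Cells of both libraries were clustered together with scanpy. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were used, with 30 principal components, 20 neighbours and Leiden resolution 1.0. These left out T cell receptor, immunoglobulin, mitochondrial and ribosomal protein genes, a list of 6 sex-linked genes (Xist, Tsix, Ddx3y, Uty, Kdm5d and Eif2s3y) and Rpa1. The 18 clusters were named from marker lists fixed before the data were examined. The scoring rule was chosen after the data were seen. A cluster took the class with most markers among its 10 leading genes by fold, counting genes with a UMI in at least 25% of its cells, and ties went to the higher mean fold of the markers. A class needed at least 2 such markers or a mean fold above that of the other cells, a condition added after a small interferon-led cluster tied for a class whose markers were low in it.

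For each class UMIs were summed per library and given as CPM, scaled to the sum of all UMIs of the class in that library. With 1 library per group there is no test across animals, and no p-value is given. Ratios carry the exact 95% conditional binomial interval of 2 Poisson counts, levels an exact Poisson interval and shares an exact Clopper-Pearson interval. All of these cover counting error only and say nothing of variation between mice. The intervals of UMI ratios and levels, and the ranges of gene list medians given next, treat UMIs as independent. They therefore also leave out the spread between cells. Gene list medians used log2 ratios with 5 CPM added, over members with at least 20 UMIs, with a 95% range from 1000 Poisson resamplings. Each median was placed among those of 10000 random lists of equal size matched on expression in 20 bins.

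Genes were named by a rule of size fixed at the same time as the marker lists. In all kept cells and in the resting DP, cycling, CD69-stage and mature T classes, they had at least 100 UMIs over both libraries, at least 20 CPM in the higher library and an interval that excluded a ratio of 1. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor segment and unnamed genes and the 6 genes of the sex-linked list were left out. Other genes on the sex chromosomes, such as Mid1, were kept. The 8 highest and the 8 lowest by the interval bound nearest to 1 were taken, and up to 4 members of each list described. Some genes that this rule takes are not reported here. Other genes are said to have been chosen after their values were seen.

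The ratio interval was tested on simulated counts for the knockout against WT comparison over all barcodes, with 11179 genes in the step. For 50 genes changed 1.25-fold the interval covered the true ratio in 96% and excluded 1 on the right side in 92%. For 50 genes changed 2-fold these shares were 96% and 100%. Over the unchanged genes the interval covered 1 in 95.1%. Counts were drawn as Poisson counts, which is the model the interval assumes. The test therefore checks the calculation only and not the spread between cells or mice.

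Alternatives fixed beforehand covered the mitochondrial limit, the gene minimum, doublets, Leiden resolution, clustering of each library alone, TMM scaling in edgeR 4.0.16, CPM without mitochondrial and ribosomal protein genes, the mean over cells of CPM per cell, thinning of each cell to 2000 UMIs, the pseudocount, the UMI minimum of lists and the depth and threshold of the cycling measure. Clustering without the 100 genes that differed most between the libraries, Rpa1 within reclustered classes and a stricter cycling list were added after the data were seen. The position test of neighbouring genes and the rules behind it were also set after the data were seen. Gene differences were not compared in the early DN, innate-like and B cell or plasma cell-like classes, which hold few cells.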

Results

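The data are 2 droplet libraries of thymus immune cells, 1 from WT mice and 1 from mice with a conditional Rpa1 knockout. Kept cells had a median of 5030 UMIs and 2183 genes in the WT library and 5082 UMIs and 2171 genes in the knockout library. Mitochondrially encoded genes took a median of 4.11% and 4.22% of UMIs. Each group has 1 library, so a difference between them cannot be set against a spread between mice, and every interval here covers counting error only. Directions describe these libraries.

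The first question was how far Rpa1 transcripts were lower in the knockout library. Rpa1 (ENSMUSG00000000751) lies on the minus strand of chromosome 11, from 75298166 to 75348324 in GRCm38. Over all kept cells it stood at 56.8 CPM in the WT library (1849 UMIs, 95% interval 54.2 to 59.5) and at 46.9 CPM in the knockout library (1682 UMIs, 44.7 to 49.2). The log2 ratio was -0.28, with an interval from -0.37 to -0.18. Among the named classes with over 100 Rpa1 UMIs in each library, the main setting gave the lowest ratio in mature T cell-like cells, where Rpa1 stood at 52.0 CPM in WT and 28.9 CPM in the knockout library, a log2 ratio of -0.85 (-1.17 to -0.54). In cycling thymocyte-like cells it was 96.6 CPM in WT and 73.4 CPM in the knockout library, with a log2 ratio of -0.40 (-0.53 to -0.26), and of -0.54 with cells weighted alike and -0.72 with each cell thinned to 2000 UMIs. Resting double-positive (DP) cells gave -0.26 (-0.44 to -0.08) and CD69-stage cells -0.38 (-0.71 to -0.05). The CD69-stage value depended on the setting, at -0.84 with doublets kept, where the mature T value was -0.61, and at -0.74 clustered without the 100 genes that differed most between the libraries. In early double-negative (DN) thymocyte-like cells both libraries held 12 Rpa1 UMIs, too few to tell the levels apart. The labels do not say which exons were removed, and a 3' tag may lie outside the deleted part, so these values do not measure how many cells lost the protein.

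**Figure D1:**
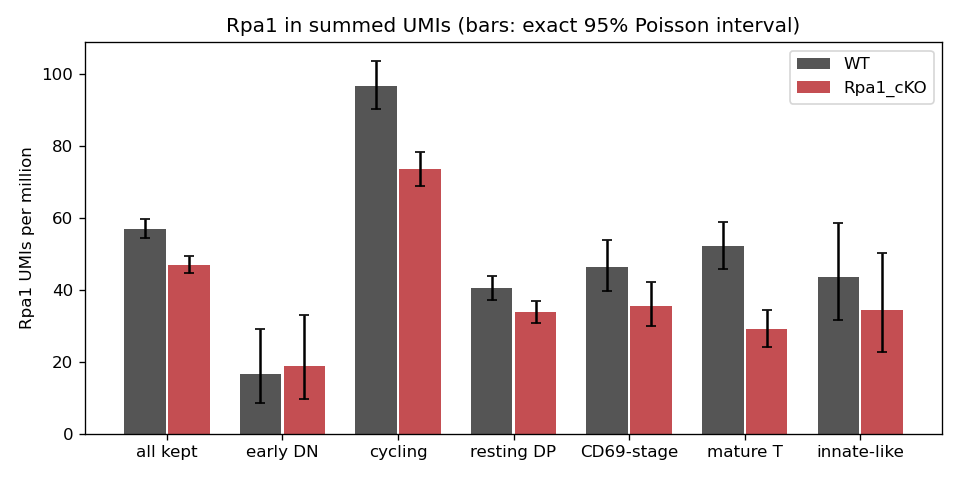
Rpa1 CPM (y axis) in summed UMIs of each cell class (x axis) for the WT and the knockout library, with exact 95% Poisson intervals as bars. Mature T cell-like cells stood at 52.0 CPM in WT and 28.9 CPM in the knockout library.

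The next comparison asked whether the make-up of the thymus differed between the libraries. Cycling thymocyte-like cells, led by genes such as Esco2, Cenpf and Mcm3, made up 8.62% of WT cells (399 of 4628, 7.83 to 9.47) and 12.8% of knockout cells (611 of 4767, 11.9 to 13.8). The share was 1.49 times as high in the knockout library, with an interval from 1.31 to 1.69. Cluster 13 of this class, with 48 WT and 81 knockout cells, had Ccnb2 and Cenpa among its leading genes. Its class markers nevertheless had a mean log2 fold of -0.91, below the other cells, against 0.41, 2.82 and 1.52 in clusters 9, 12 and 15 of the class. Resting DP cells, which express Rag1 and are the main thymocyte stage, made up 63.1% (61.7 to 64.5) and 60.2% (58.8 to 61.6). These exact intervals do not overlap, so the share was slightly lower in the knockout library beyond counting error. The ratio was 0.953 (0.905 to 1.004), but its interval treats cell numbers as Poisson counts and is too wide for so large a share. CD69-stage cells made up 13.8% and 14.4%, a ratio of 1.04 (0.936 to 1.16). Of these, 490 cells formed cluster 10, led by Nr4a1 with Cd69 and Egr2 among its leading genes, and 838 formed cluster 8, led by Tox, Arap2 and Edaradd, where the class markers had a mean log2 fold of only 0.33 over the other cells. Mature T cell-like cells made up 11.7% and 10.5%, a ratio of 0.897 (0.793 to 1.02). Of these, 732 cells formed cluster 0, led by Itm2a, Id2 and Il7r, where the class markers had a mean log2 fold of only 0.79. The other 309 formed cluster 1, with S1pr1 and Klf2 among its leading genes and a mean log2 fold of 2.26. Early DN cells numbered 41 and 34, and innate-like cells, marked by Nkg7 and Klrd1, 73 and 53, and in both cases the interval of the ratio included 1. A B cell or plasma cell-like cluster held 12 cells in each library. The CD69-stage and innate-like shares depended on the cell filter and the clustering. With at most 5% mitochondrial UMIs their log2 ratios had the opposite sign to the main 0.06 and -0.50, at -0.14 for CD69-stage and 1.24 for innate-like cells, and with at least 1000 genes per cell the innate-like value was 0.96. With each library clustered alone, 84 WT cells and 0 knockout cells were named innate-like, and the CD69-stage class held 282 and 487 cells, whereas the cycling class held 402 and 628. Clustered without the 100 genes that differed most between the libraries, the cycling class held 402 and 616 cells and the mature class 256 and 218.

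**Figure D2:**
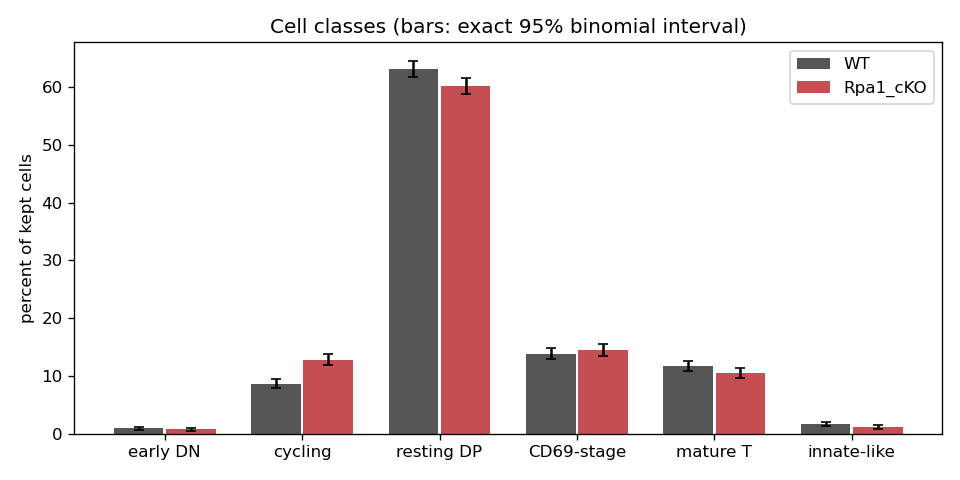
Percent of kept cells (y axis) in each named class (x axis) for the WT and the knockout library, with exact 95% binomial intervals as bars. The cycling class was 8.62% of WT and 12.8% of knockout cells.

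A second measure of cycling counted cells with UMIs of listed cell cycle genes. As fixed beforehand, with at least 2 UMIs after thinning to 2000 UMIs, the G2/M list marked 96.6% of cells in each library (4400 of 4556 WT and 4542 of 4701 knockout cells, with 72 and 66 shallower cells left out). It also marked 88.7% of WT mature T cell-like cells, so the measure was saturated and does not tell cycling cells apart. Without thinning it marked 99.9% and 99.8%. Listed genes such as Smc4, Jpt1, Ctcf and Lbr had UMIs in resting cells, with a mean of 0.683 UMIs of Smc4 per thinned mature T cell-like cell. The DNA replication list, which marked 66.8% and 67.2% of cells after thinning and 95.1% and 94.6% without it, marked 59.3% of WT mature T cell-like cells after thinning and had the same limit. A stricter list, chosen after this was seen and from levels in mature T cell-like cells rather than from the comparison, kept 36 G2/M genes with at most 0.02 UMIs per such cell. With it, 9.68% of WT cells (8.84 to 10.6) and 14.6% of knockout cells (13.6 to 15.6) had at least 2 UMIs, a ratio of 1.503 (1.33 to 1.70). Since the genes were chosen for low levels in mature T cell-like cells, the 0.743% and 1.60% marked there, at median depths before thinning of 8221 and 8070 UMIs, are low by that choice and are no independent background. With 18 stricter replication genes the shares were 7.46% and 10.4%, a ratio of 1.40 (1.21 to 1.61). Among cycling cells, 91.5% of WT and 94.3% of knockout cells were marked by the stricter G2/M genes. Many of these genes, such as Mki67, Cenpf and Tpx2, are also markers that name the cycling class. The high shares there follow in part from that naming, and this measure is not independent of the class share. Among resting DP cells the stricter G2/M genes marked 1.89% and 3.09%, and the stricter replication genes 1.26% and 0.888%. Among CD69-stage cells the stricter G2/M genes marked 2.22% of WT cells (14 cells) and 0.884% of knockout cells (6 cells). The ratio of 0.399 had an interval from 0.126 to 1.105, which included 1. The stricter replication genes marked 0.633% and 0.884% there.

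**Figure D3:**
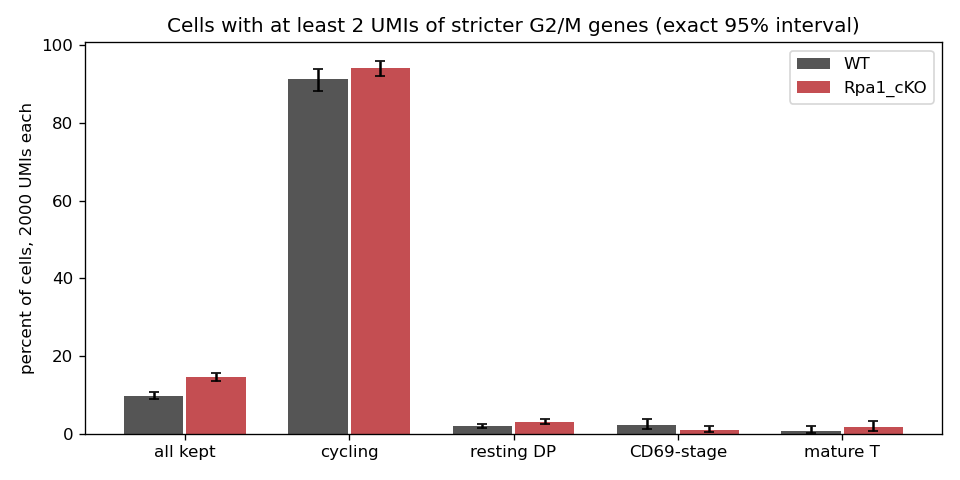
Percent of cells, each thinned to 2000 UMIs, with at least 2 UMIs of the stricter G2/M genes (y axis) in all kept cells and 4 classes (x axis), with exact 95% binomial intervals as bars. Over all kept cells the share was 9.68% in WT and 14.6% in the knockout library.

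Over all kept cells the genes of the cell cycle lists were higher in the knockout library. Of 58 measured G2/M genes 55 had a higher CPM there, 52 of them with an interval that excluded a ratio of 1, with a median log2 ratio of 0.44 (range 0.41 to 0.47), above all 10000 random lists. Examples are Birc5, a subunit of the chromosomal passenger complex, at 153 and 232 CPM, and Tpx2, a spindle factor, at 65.1 and 104 CPM. Of 51 DNA replication genes 47 were higher, 42 with an interval above 1, with a median of 0.29 (0.26 to 0.31), among them Tk1 at 29.99 and 46.5 CPM and Rrm2, a subunit of ribonucleotide reductase, at 199 and 277 CPM. The replication median was 0.17 with cells weighted alike and 0.20 with each cell thinned to 2000 UMIs. All 36 replication-dependent histone genes were higher, with intervals above 1 and a median of 0.44 (0.43 to 0.49), and Hist1h4d stood at 491 and 850 CPM. Maturation and egress genes were lower over all cells, with a median of -0.21 (-0.24 to -0.17), below all random lists, and of -0.0862 with each cell thinned, and S1pr1, the receptor used in exit from the thymus, stood at 23.0 and 15.6 CPM. These values mix the class shares with levels inside a class. Within the cycling class the replication median was -0.03 (percentile 8.42), and 0.00452 with each cell thinned to 2000 UMIs, and the G2/M median 0.09 (0.07 to 0.10), with Hmgb2 at 6406 and 7175 CPM and Cenpa at 321 and 373 CPM.

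Among genes with at least 20 CPM in the higher library, Il2rb led the lower side over all kept cells. Il2rb, which encodes the beta chain of the IL-2 and IL-15 receptors, stood at 104 CPM in WT and 5.63 CPM in the knockout library, a log2 ratio of -4.21 (-4.43 to -4.01). Wnt8b, below that limit at 12.8 and 0.195 CPM, had a log2 ratio of -6.03 (-7.35 to -4.97). Ero1lb was at 35.98 and 4.93 CPM, Cdk5rap1 at 34.1 and 6.38 CPM, and Slc15a2 at 22.2 and 5.66 CPM. Gnb4, Arl3 and Pdlim1 were also lower in the knockout library, with log2 ratios of -1.25, -1.18 and -0.85. Cd74 had a log2 ratio of -0.94 over all kept cells, but it led the B cell or plasma cell-like cluster, whose 12 cells per library had medians of 13019.5 UMIs in WT and 6133 in the knockout library, and in mature T cell-like cells it stood at 22.2 and 23.7 CPM. The 8 genes that the naming rule took on the higher side were Fbxw10, at 6.91 and 22.5 CPM, Hist2h4, Jun, Csrp1, Itgb3bp, Egln3, Cep55 and Hist1h4d. Jun, an immediate-early transcription factor, stood at 32.9 and 64.9 CPM, and Csrp1 at 103 and 197 CPM.

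In resting DP cells Il2rb had 1492 UMIs in WT and 1 UMI in the knockout library, a log2 ratio of -10.50 with an interval from -15.81 to -8.02. Wnt8b stood at 21.1 and 0.446 CPM and Ero1lb at 63.0 and 3.94 CPM. Cdk5rap1, Slc15a2, Pdlim1, Arl3 and Gnb4 had log2 ratios from -2.54 to -1.29. On the higher side were Fbxw10 at 12.3 and 47.1 CPM, Eps8l1 at 5.14 and 21.0 CPM, Insl5 at 7.60 and 28.7 CPM and Csrp1 at 89.7 and 209 CPM. Jun, Pttg1, Mbnl1 and Nfia followed, and Mbnl1, a splicing factor, stood at 707 and 1351 CPM. Of 13 measured V(D)J recombination and end-joining genes 9 were lower, 7 with an interval below 1, with a median of -0.16 (-0.20 to -0.04, percentile 0.06). Rag1, a subunit of the V(D)J recombinase, stood at 3453 and 2824 CPM and Rag2 at 306 and 260 CPM. T lineage transcription factors had a median of -0.09 (-0.12 to -0.06), with Tcf7 at 1665 and 1416 CPM and Lef1 at 349 and 305 CPM. Nuclear genes of oxidative phosphorylation had a higher CPM for 46 of 50 members, 29 with an interval above 1, with a median of 0.07 (0.06 to 0.09), such as Cox5b at 340 and 381 CPM. In the main clustering, different clusters held most of this class in each library. Knockout cells made up 89.9% of cluster 3, which had 0 of its class markers among its leading genes, and 65.0% of cluster 5, but 14.7% of cluster 7, 27.6% of cluster 6 and 32.9% of cluster 2. Cluster 4 was led by Jun at a median of 2258 UMIs, and cluster 14, with 28 cells, by Ifit1, Usp18 and Isg15. The split between the libraries was smaller when the genes that differed most between them were left out of clustering. Knockout cells then made up 40.2% to 60.8% of each resting DP cluster.

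In cycling cells type I interferon response genes were higher in the knockout library. Of 28 measured members 22 had a higher CPM there, 9 with an interval above 1, with a median of 0.18 (0.10 to 0.25), above all random lists. Isg15, a ubiquitin-like protein induced by interferon, stood at 11.5 and 30.6 CPM, Usp18 at 1.44 and 6.53 CPM and Ifit1, with 1 and 59 UMIs, had a log2 ratio of 5.29 (2.76 to 10.62). In resting DP cells 21 of 30 members were higher, 15 with an interval above 1, with a median of 0.13 (0.10 to 0.21), and Isg15 stood at 9.48 and 17.4 CPM. In mature T cell-like cells 26 of 38 were lower, 10 with an interval below 1, and the median was -0.12 (-0.19 to -0.04), with Ifi213 at 37.2 and 20.3 CPM. That direction turned when each cell counted alike, with a median of 0.032. With each cell thinned to 2000 UMIs the median was 0.097, but over the members that still had at least 20 UMIs after thinning. Clustered without the 100 genes that differed most between the libraries the median was -0.00445. In CD69-stage cells 11 of 24 members were higher, 1 with an interval above 1, with a median of -0.04 (-0.11 to 0.08). Over all kept cells, which mix in the class shares, 14 of 39 were higher, 5 with an interval above 1, with a median of -0.05 (-0.11 to -0.02), which also turned, to 0.0208 with cells weighted alike and 0.012 with cells thinned. The mature T class joined 2 clusters in unequal parts: cluster 1, with Igfbp4, S1pr1, Klf2 and Ifi27l2a among its leading genes, held 181 WT and 128 knockout cells, and cluster 0, led by Itm2a, Id2 and Il7r, held 360 and 372. Replication-dependent histones had medians of 0.22 (0.18 to 0.25) in cycling cells and 0.18 (0.12 to 0.21) in resting DP cells, where the value was 0.11 with at most 5% mitochondrial UMIs. They were 0.33 (0.20 to 0.40) in CD69-stage cells and 0.21 (0.08 to 0.28) in mature T cell-like cells, where the value was 0.0161 with each cell thinned and 0.47 with at most 5% mitochondrial UMIs. All 4 main values lay above all random lists. Notch targets and beta selection genes had a median of -0.18 (-0.21 to -0.10) in cycling cells, with Dtx1, a Notch target, at 8.16 and 3.11 CPM and Ptcra, the pre-T cell receptor alpha chain, at 116 and 88.9 CPM. Named genes on the higher side in cycling cells included Isg15, Mbnl1, As3mt, Mid1, Hist2h4, Hist1h4n and Egln3. Those on the lower side were Il2rb, with 195 and 2 UMIs and a log2 ratio of -7.20 (-10.25 to -5.33), Cdk5rap1, Dqx1, Arhgef40, Gnb4, Arl3, Lgals8 and Pttg1. The direction of Arhgef40 turned with each cell thinned to 2000 UMIs, where its log2 ratio was 0.0945. Pttg1, which encodes securin, an inhibitor of separase, stood at 195 and 123 CPM in cycling cells but at 16.7 and 38.5 CPM in resting DP cells.

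In CD69-stage cells Eps8l1, Jun, Mbnl1, Csrp1, Egln3, Mirt1, Cxxc5 and Trim59 were higher in the knockout library, with log2 ratios from 0.73 to 1.79. Il2rb, Ero1lb, Cdk5rap1, Pdlim1, Prss2, Gnb4, Sfxn3 and Edaradd were lower, with Il2rb at 151 and 3.07 CPM. Prss2 had a log2 ratio of -1.68, and of 0.45 with doublets kept. T cell receptor signal response genes had a median of -0.05 (-0.10 to 0.01), with Cd69 at 284 and 361 CPM and Nr4a3 at 87.3 and 63.9 CPM.

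In mature T cell-like cells Akr1c18 stood at 29.4 and 1.58 CPM, Il2rb at 177 and 22.6 CPM and Edaradd at 91.1 and 24.2 CPM. Cdk5rap1, Pdlim1, Lgals8, Rnpep and Aff3 were also lower in the knockout library. Pclaf, a factor that binds the replication clamp, stood at 3.70 and 28.0 CPM and Nrgn at 11.1 and 47.6 CPM. Nrgn had a log2 ratio of 2.10, and of -0.27 at Leiden resolution 2.0. Jun, Egln3, As3mt, Cxxc5, Arhgap5 and Mbnl1 were the other genes on the higher side. Of 48 measured DNA replication genes 45 had a higher CPM, 17 with an interval above 1, with a median of 0.31 (0.21 to 0.35), and Gmnn stood at 22.0 and 36.6 CPM. The median was 0.14 with each cell thinned to 2000 UMIs, 0.15 with cells weighted alike and 0.54 with each library clustered alone. The stricter replication genes marked 1.49% of WT and 2.20% of knockout cells of this class, a ratio of 1.48 (0.543 to 4.25). How far such cells add to the median was not tested. Nuclear genes of oxidative phosphorylation had a higher CPM for 47 of 50, 33 with an interval above 1, with a median of 0.15 (0.13 to 0.18), such as Uqcrq at 368 and 474 CPM. Foxp3, the regulatory T cell factor, stood at 7.40 and 16.7 CPM. Il2rb, lower in these cells as given above, is on the same list of regulatory T markers. No cluster was named regulatory T, and the share of such cells was not measured.

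Further lists covered damage and death responses. For p53 targets the median was 0.05 (-0.02 to 0.10) in cycling cells, -0.02 (-0.05 to 0.05) in resting DP cells, -0.13 (-0.21 to -0.01) in CD69-stage cells and 0.06 (-0.02 to 0.17) in mature T cell-like cells. Pmaip1, a pro-apoptotic p53 target, stood at 1.78 and 3.34 CPM over all cells and Ccng1 at 42.6 and 35.0 CPM. The pro-apoptotic list had a median of -0.02 in cycling cells and 0.00 in resting DP cells. Genes of the ATR, homologous recombination and Fanconi pathways had a median of -0.02 (-0.07 to 0.02) in cycling cells, where Clspn stood at 210 and 227 CPM. Their median was -0.05 (-0.09 to 0.00642) in resting DP cells, -0.08 (-0.18 to 0.03) in CD69-stage cells and 0.13 (0.00461 to 0.17, percentile 99.7) in mature T cell-like cells. The mature T value depended on the setting, from 0.0447 clustered without the 100 genes that differed most between the libraries to 0.24 with each library clustered alone. Over all kept cells 30 of the 42 had a higher CPM, 18 with an interval above 1, with a median of 0.10 (0.06 to 0.14), above all random lists, a value that mixes in the class shares and was 0.012 with cells weighted alike.

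**Figure D4:**
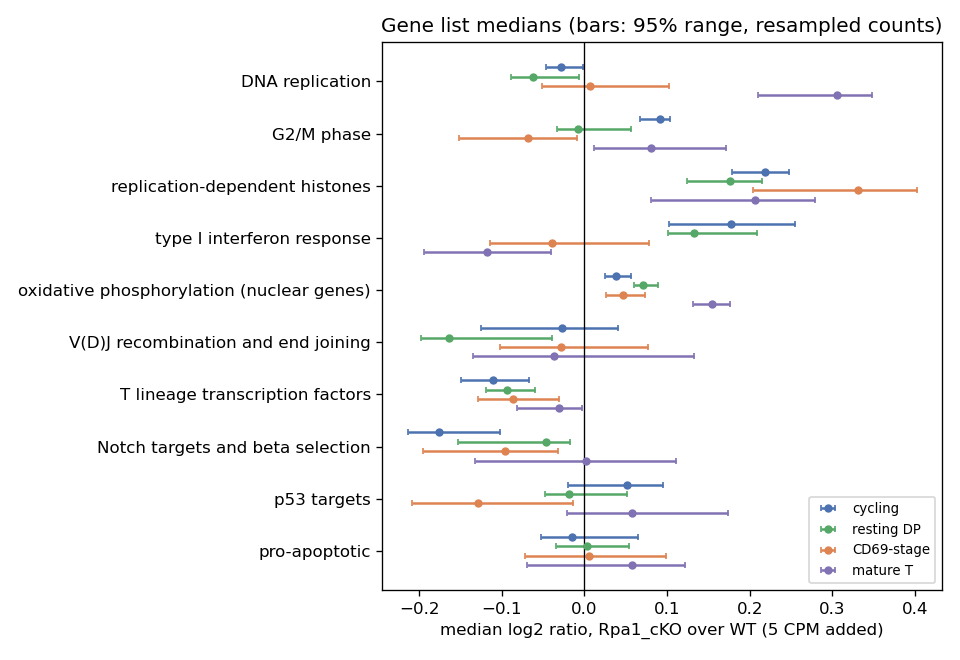
Median log2 ratio of the knockout over the WT library (x axis, 5 CPM added) for 10 gene lists (y axis) in 4 cell classes (points), with 95% ranges from resampled counts as bars. Replication-dependent histones lay at 0.22 in cycling and 0.18 in resting DP cells, and p53 targets at 0.05 and -0.02.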

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

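The segment tests, the count of genes in each direction, the doublet test, the S phase test and the test of free interferon RNA were chosen only after the results they bear on were seen. Medians of some gene lists went opposite ways in different classes, and in each case the difference was not tested. For maturation and egress genes the resting DP median (0.10) minus the cycling median (-0.12) was 0.227, and this difference was not tested. For ribosomal protein genes the resting DP median (0.10) minus the mature T median (-0.08) was 0.176, and the CD69-stage median (0.10) minus the mature T median was 0.182, and these differences were not tested.

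Genes such as Il2rb, Wnt8b and Cdk5rap1 had ratios far from 1 in several classes, and neighbours among such genes had been noticed before their positions were tested. With intervals beyond 2-fold in at least 3 of 4 classes there were 10 genes and 1 pair lying 100 kb to 5 Mb apart, against a median of 0 and an upper limit of 2 for the central 95% of 10000 expression-matched random sets, which cannot decide. A wider definition, set because of that outcome, took 48 genes beyond 1.5-fold in at least 2 classes, and these made 26 pairs against a median of 6 and a highest random count of 20, for example Lgals8, Edaradd, Ero1lb and Gpr137b on chromosome 13 and Pdlim1, Wnt8b, Sfxn3 and Arl3 on chromosome 19. Since the neighbours prompted the test, chromosome segments that differ between the animals remain a hypothesis drawn from these data. They are a candidate explanation for part of these genes only, although both libraries are labelled C57BL/6. Within 20 Mb of Rpa1 there were 3 such genes, Shmt1, Trim16 and Fbxw10, against a random median of 1 and an upper limit of 4. These lie from 60788104 to 62877465 on chromosome 11, and Trim16 and Fbxw10 overlap. Ubb, reported further below, starts at 62551171 in the same stretch. Whether this stretch differs between the animals was not tested. Of the 10 genes of the first definition 4 were higher and 6 lower in the knockout library. That argues against free RNA of another cell type in 1 library as the cause in both directions, while within 1 direction it stays open. Of these genes 40% (12.2 to 73.8) differed by a like CPM amount in the classes of highest and lowest level, too few genes to tell from 50%. The measure also cannot decide because a like number of free UMIs per cell makes unlike CPM where depth differs. Median depths in WT were 18096 UMIs in cycling and 4499 UMIs in resting DP cells. An effect of the genotype was not tested and stays open too.

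The cycling class was larger in the knockout library. A difference in UMIs per cell is argued against, since with every cell thinned to 2000 UMIs the share with stricter G2/M genes was 1.503 times as high (1.33 to 1.70). With the highest scoring barcodes kept the log2 ratio of the shares was 0.615 against 0.57 without them, so the larger class did not rest on those barcodes. Doublets as such cannot be excluded, since those with lower scores stay in both settings. Cells held in S phase cannot be told apart from an equal phase mix: cluster 9, where replication genes led G2/M genes, held 24.1% of knockout and 29.3% of WT cycling cells, but cluster 12, with 312 and 187 cells, had replication genes at 1.15 times the class level against 1.11 in cluster 9, so this split does not measure S phase. The genotype, the age or handling of the animals and the sampling of the organ may each account for the larger class, and 1 library per group does not separate them.

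Interferon response genes had medians above 0 in cycling and resting DP cells and below 0 in mature T cell-like cells of the knockout library. In CD69-stage cells the direction was not detectable, at -0.04 (-0.11 to 0.08). The small interferon-led cluster does not account for the resting DP value, since without it the median was 0.139 (0.05 to 0.18). Free interferon-induced RNA cannot be told apart from expression. The mature median of -0.118 would argue against it, but became 0.032 with cells weighted alike and -0.00445 clustered without the most differing genes. With cells thinned the mature median was 0.097, over the members that still had enough UMIs after thinning. An effect of the genotype and the unequal mix of the mature T clusters may contribute, and neither was tested.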

How the results depend on the processing

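Clustering without the most differing genes, the stricter cycling lists and the Rpa1 values in reclustered classes were chosen after seeing the data. No paired analysis was possible because each group has 1 library, so no test was run. The Rpa1 ratio kept its direction under every alternative run where its interval excluded 1: of 75 Rpa1 values under alternatives 70 stayed within the counting interval, 5 lay outside it, such as -0.72 in cycling cells thinned to 2000 UMIs, and 0 turned. Of 44 class share values 39, 5 and 0 did so, of 16 cycling list values 14, 2 and 0, of 1957 list medians 1706, 223 and 28, and of 893 named gene values 800, 89 and 4. Only values whose main interval excluded a ratio of 1 were counted as turned. Among the others the sign was opposite to the main one for 3 Rpa1 values, 7 class shares, 6 cycling list values and 208 list medians. Depth limits the classes with few cells, and the full cycling lists mark most resting cells, so their small movement under other filters, depths and UMI minimums says nothing of stability. The values that follow are log2 medians of gene lists, log2 ratios of named genes or log2 ratios of class shares (share), with the cells in parentheses (all means all kept cells), and for each the cause was not tested. Thinned list medians took only members that still had at least 20 UMIs after thinning, so they can cover fewer genes than the main values.

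With each cell thinned to 2000 UMIs these were 0.20 for DNA replication (all), 0.25 for histones (resting DP), 0.14 for DNA replication (mature T), and with the sign turned -0.0148 for RPA complex (all), 0.012 for interferon (all), 0.041 for thymic stress (all), 0.0945 for Arhgef40 (cycling), 0.0269 for RPA complex (cycling), 0.00452 for DNA replication (cycling), -0.0406 for G2/M (mature T), 0.10 for interferon (mature T), -0.0219 for immediate-early (mature T). With TMM scaling these were 0.34 for DNA replication (all), 0.48 for G2/M (all), 0.12 for G2/M (cycling), 0.10 for oxidative phosphorylation (resting DP), and with the sign turned 1.82e-05 for DNA replication (cycling), 0.0154 for ribosomal proteins (cycling). With cells weighted alike these were 0.17 for DNA replication (all), 0.41 for G2/M (all), 0.11 for G2/M (cycling), 0.26 for histones (cycling), 0.15 for DNA replication (mature T), 0.12 for oxidative phosphorylation (mature T), and with the sign turned 0.0208 for interferon (all), 0.0105 for NF-kB targets (all), 0.0026 for TCR complex (all), 0.0317 for interferon (mature T). With a pseudocount of 1 CPM these were 0.32 for DNA replication (all), 0.51 for G2/M (all), 0.26 for interferon (cycling), 0.24 for histones (resting DP), 0.35 for DNA replication (mature T). Without mitochondrial and ribosomal protein genes in the total these were 0.47 for G2/M (all), 0.0929 for oxidative phosphorylation (resting DP). With at most 5% mitochondrial UMIs these were 0.12 for G2/M (cycling), 0.11 for histones (resting DP), 0.48 for DNA replication (mature T), -0.14 for share (CD69-stage) and 1.24 for share (innate-like), both opposite in sign to main values of 0.06 and -0.50 whose intervals included a ratio of 1, and with the sign turned -0.00688 for mitochondrially encoded (resting DP). With a minimum of 1 UMI these were 0.10 for interferon (resting DP). With doublets kept these were 0.47 for DNA replication (mature T), and with the sign turned 0.45 for Prss2 (CD69-stage), 0.0345 for T lineage factors (mature T). With each library clustered alone these were 0.54 for DNA replication (mature T), -0.15 for share (resting DP), 0.75 for share (CD69-stage), and with the sign turned 0.0634 for G2/M (CD69-stage), 0.14 for Notch (CD69-stage), -0.24 for immediate-early (CD69-stage), -0.0356 for oxidative phosphorylation (CD69-stage), 0.0254 for maturation (mature T). With at least 1000 genes per cell these were 0.42 for DNA replication (mature T), 0.96 for share (innate-like), again opposite in sign, and with the sign turned -0.0205 for immediate-early (CD69-stage), 0.00487 for T lineage factors (mature T). At Leiden resolution 2 these were 0.18 for oxidative phosphorylation (mature T), and with the sign turned -0.27 for Nrgn (mature T), 0.0139 for T lineage factors (mature T). Clustered without the most differing genes these were 0.44 for DNA replication (mature T), -0.00445 for interferon (mature T), 0.18 for oxidative phosphorylation (mature T), and with the sign turned -0.0485 for Nrgn (mature T), 0.0511 for T lineage factors (mature T). With at most 20% mitochondrial UMIs these were 0.44 for DNA replication (mature T), and with the sign turned 0.00351 for T lineage factors (mature T). At Leiden resolution 0.5 these were 0.51 for DNA replication (mature T), and with the sign turned -0.0138 for TCR signal response (mature T), 0.00604 for T lineage factors (mature T). With the stricter lists these were 0.59 for marked cells (G2/M list), 0.48 for marked cells (DNA replication list).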

Other observations

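The test of the Gm8797 counts and the choice of Gm8797 and Ubb, which the naming rule does not take, were decided on after their values were seen. Several other gene groups differed in single members. Zap70, a kinase of T cell receptor signalling, was higher in the knockout library in all 4 compared classes, at 61.4 and 102 CPM in resting DP cells, and Ptprc, which encodes CD45, was lower in all 4, at 1266 and 1072 CPM there. The heat shock genes Hspa8 (1921 and 1506 CPM over all cells) and Hsph1 (84.5 and 56.1 CPM) were lower, while the immediate-early genes Jun and Fosb (2.77 and 5.80 CPM) were higher. Their whole list of dissociation and immediate-early genes had 11 members higher and 10 lower over all cells, with a median of 0.005 (-0.03 to 0.04). Endoplasmic reticulum stress genes had a median of -0.15 (-0.22 to -0.04) in CD69-stage cells, with Hspa5 at 200 and 167 CPM. Anti-apoptotic genes had a median of -0.13 (-0.23 to -0.04) in the same cells, but of -0.00236 at Leiden resolution 0.5, with Bcl2a1d at 32.3 and 16.1 CPM, whereas Bcl2 in mature T cell-like cells stood at 435 and 556 CPM.

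Cytosolic DNA sensing genes had a median of 0.26 (0.07 to 0.35) in CD69-stage cells, where 0 of 10 measured members had an interval that excluded 1, and the median was 0.0171 at Leiden resolution 2 and 0.019 with doublets kept. Cholesterol synthesis genes had a median of -0.13 (-0.19 to -0.06) in cycling cells, with Msmo1 at 27.7 and 19.7 CPM. Glycolysis genes had a median of -0.08 (-0.11 to -0.03) there, with Eno1 at 202 and 171 CPM. Of 80 ribosomal protein genes 78 had a higher CPM in resting DP cells, 73 with an interval above 1, and 72 a lower CPM in mature T cell-like cells, 64 with an interval below 1. Ccl5, which encodes a chemokine, had 46 and 542 UMIs over all cells. Of 5 measured genes of the sex-linked list 4 had a lower CPM over all cells and 1 a higher one. Eif2s3y on the Y chromosome stood at 107 and 57.4 CPM and Ddx3y at 117 and 89.7 CPM. Gm47283, outside that list and placed by the annotation on the Y chromosome from 90784738 to 90816464, stood at 323 and 519 CPM. Whether its reads come from that chromosome alone was not tested, so it is not set against Eif2s3y and Ddx3y.

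Gm8797 on chromosome 3 had 441 UMIs in the WT library and 20663 in the knockout library, at 13.5 and 576 CPM, while Ubb, a ubiquitin gene on chromosome 11, stood at 2482 and 2006 CPM. The log2 ratio of their summed CPM over all kept cells was 0.0492, so reads shared between them, together with a sequence variant in the knockout library, are a candidate explanation. In mature T cell-like cells the sum had a log2 ratio of 0.11. No sequence reads were examined, and the variant was not tested.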
